A study of Rattus norvegicus with 9 samples.

How the data were processed

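Gene expression was measured by RNA sequencing in primary cardiomyocytes from the ventricles of newborn rats under stimuli of hypertrophic growth. The cells received vehicle, 50 µM phenylephrine or 10 nM IGF1 for 48 hours, and each of the 3 groups had 3 samples. Per the labels' protocols, total RNA was made into libraries with a NuGEN Ovation kit and sequenced on an Illumina NovaSeq instrument. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 samples of a group came from separate cultures or litters, so the p-values measure the spread between these samples, which may be technical.

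The deposited values are raw read counts per gene, whole numbers with no normalization, in a table of 17327 rows and a column for each of the 9 samples. Per the submitters' processing notes, STAR, HTSeq and DESeq were used with the rn5 build of the rat genome. The notes give neither versions nor the role of each tool, and whether counting used strand is not given in the sources used here. Genes are named by symbol only. Of the symbols, 14811 matched a RefSeq gene table of another rat build (GRCr8), 2100 matched only an older name in it and 416 matched none, so no coordinates are given. A further limit is that 26 rows carry gene names turned into calendar dates by spreadsheet software, in 24 distinct forms, and these genes are not named here. No row held unassigned reads or totals. Reads shared between near-identical copies (Acta1 and Actc1, Myh6 and Myh7, Scd1 and Scd2) can be split or lost by such counting, so their values are uncertain.

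Total counts ran from 31274396 to 48505265 per sample. A level of 1 CPM, the unit of edgeR's cpm function, scaled here by the normalization factors below, rested on 29.1 to 51.6 reads. Genes were kept by the filterByExpr function of edgeR with its defaults (minimum count 10, minimum total count 15), which left 11873 genes holding 99.99% of the counts. Counts were normalized by the trimmed mean of M-values (TMM) in edgeR 4.0.16 and fitted with a robust quasi-likelihood model of group over all 9 samples. Each pair of groups was tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Every adjusted p for a gene is from this test unless another is named. Each SE is the absolute log2 fold change divided by the square root of the F statistic. It thus reflects the spread over all 9 samples, also those outside the comparison. Levels are CPM as mean ± SD over the 3 samples of a group. R 4.3.3 was used.

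Before the data were examined, 21 gene lists and 7 lists of cell type markers were fixed and tested with camera in limma 3.58.1, which compares a list with all other genes, with a preset correlation between genes of 0.01. The p-values were adjusted over the 28 lists of a comparison. The test was repeated with the correlation estimated for each list. The tests, alternatives and the rule for naming genes were fixed at the same time. The rule took the 8 genes with the largest rise and the 8 with the largest fall against vehicle (6 and 6 for phenylephrine against IGF1) among genes past the threshold, with a mean of at least 5 CPM in a group, no overlap between the groups' samples and a named symbol. Chance gives such separation for 10% of genes in groups of 3. It also took from each list up to 4 members, the 2 highest and 2 lowest past the threshold or otherwise the member with the smallest adjusted p, and always Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Rcan1, Adra1a, Adra1b, Igf1r, Gfpt1 and Atf4. Genes named outside this rule are said to be so.

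The alternatives were DESeq2 1.42.0, limma-voom, other normalization factors, scaling by library size only, no filter and a stricter filter, a fit of the 2 groups compared alone, the replicate number as a block, other thresholds, the estimated correlation, and leaving out each sample in turn. Counts for 9 samples were simulated from the gene means and sizes of all 9 samples, with a spread set by level alone. Of the 11788 genes tested, 48 to 50 were changed at each fold in the treated group. A further list of 20 genes was raised by log2 0.3. With phenylephrine as the treated group, the edgeR test against vehicle recovered 41.7% of genes changed 1.25-fold and 87.8% of those changed 1.5-fold. It recovered 90% at 2-fold and 100% at 3-fold, with 7 false among 172 calls. With IGF1 as the treated group the shares were 49.0%, 80%, 91.8% and 98%, with 10 false among 180 calls. Far more genes were called in the data than were changed here, so these shares need not hold there. Some list members have no row in the table (Ttn, Tcap, Xirp1, Idh3b, Mef2c, Rrp12, Col4a2, Col6a1, Cenpe, Tnfaip3, Upk3b and others), and the erythroid list kept 1 tested gene. Because both treatments share the vehicle samples, the correlation of their fold changes was set beside 20 simulations of unchanged groups against shared controls.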

Results

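The series compared rat neonatal ventricular myocytes under 2 stimuli of hypertrophic growth, the alpha-adrenergic agonist phenylephrine and the growth factor IGF1, with vehicle. Total counts were 45919443, 38659775 and 48505265 in the vehicle samples, 31274396, 33607863 and 33083526 with phenylephrine, and 31987197, 42737982 and 46221459 with IGF1. The groups separated on the first pair of principal components, which held 51.2% and 26.5% of the variance. IGF1 replicate 1 stood apart from IGF1 replicates 2 and 3. Between 195 and 228 genes differed over 1.5-fold between it and either of them, against 2 to 28 genes for any other pair of samples of a group. Chi-square per degree of freedom over genes was 83.9 and 86.8 for these pairs and 3.02 to 7.42 for the others, so each pair differed by more than sampling noise.

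**Figure D1:**
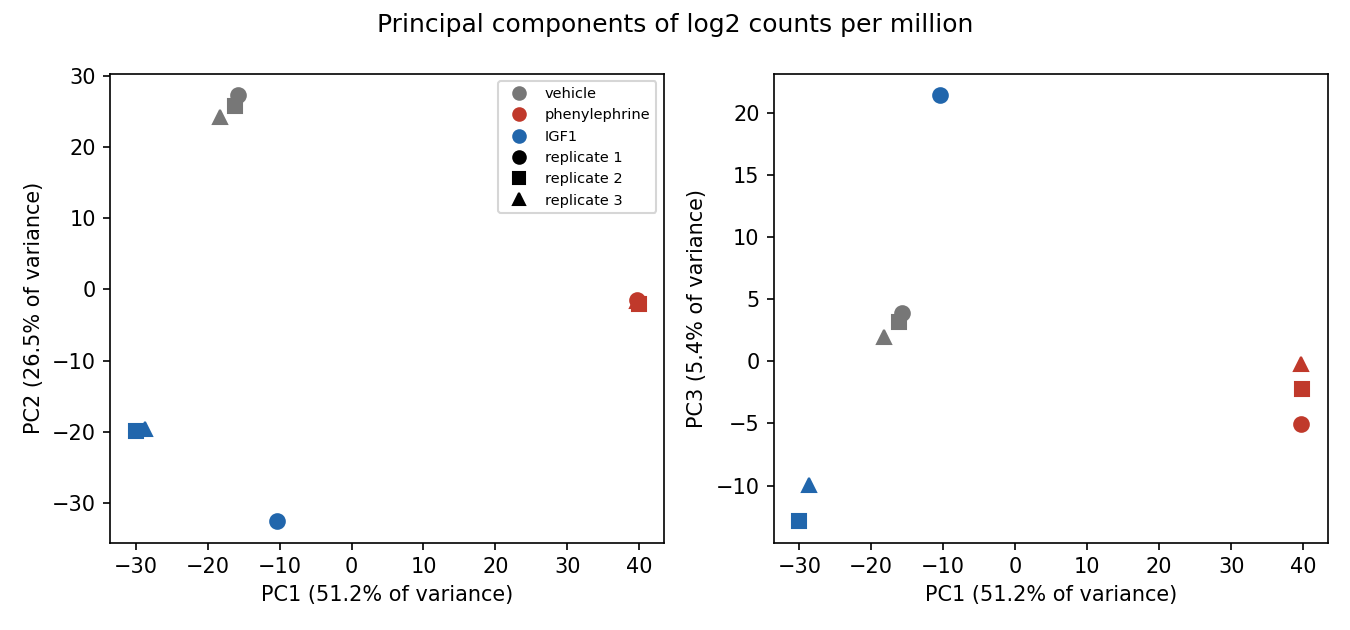
Principal components of log2 CPM, with the share of variance on each axis, for the 9 samples coloured by group and shaped by replicate number. Phenylephrine samples lie apart on the first component, and IGF1 replicate 1 lies at 21.4 on the third, where IGF1 replicates 2 and 3 lie at -12.9 and -9.93.

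Phenylephrine against vehicle addressed the response to alpha-adrenergic stimulation. The natriuretic peptide genes Nppa and Nppb, classical markers of cardiac hypertrophy, were 11.4-fold and 11.3-fold higher with phenylephrine. Nppa rose from 705 ± 46.3 to 8017 ± 227 CPM (SD, n = 3; log2 fold change 3.51, SE 0.69, edgeR adjusted p = 0.0049) and Nppb from 145 ± 9.42 to 1631 ± 34.7 CPM (3.49, SE 0.94, adjusted p = 0.019). Skeletal alpha-actin Acta1 rose 9.09-fold (adjusted p = 0.0071), the actin-binding Xirp2 11.7-fold (adjusted p = 0.018) and the calcineurin regulator Rcan1 2.30-fold (adjusted p = 0.042). The slow myosin heavy chain Myh7 rose 1.27-fold and Myh6 1.23-fold, while the calcium pump Atp2a2 was 1.53-fold lower (adjusted p = 2.6e-08). The calls of Nppb and Xirp2 ended when any 1 vehicle sample was left out (log2 3.44 to 3.59, adjusted p = 0.058 to 0.066). That of Rcan1 ended when any 1 vehicle or phenylephrine sample was left out (log2 1.15 to 1.22, 0.090 to 0.11), without a filter on low counts (0.051) and with the replicate number as a block (0.066). That of Myh7 ended without vehicle replicate 1 (0.056) and with scaling by library size only (0.070). Leaving out IGF1 replicate 1, a sample outside this comparison that enters the shared spread, gave adjusted p of 4.1e-38 for Nppb, 1.2e-06 for Xirp2, 9.6e-32 for Rcan1 and 1.0e-12 for Myh7. The log2 fold changes were then 3.50 for Nppb, 3.56 for Xirp2 and 0.35 for Myh7.

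In all, 3310 genes were higher and 3429 lower with phenylephrine, of which 361 and 492 changed at least 2-fold. All 8 tested hypertrophy markers passed the threshold as higher (8 adjusted over the list alone), with a median log2 fold change of 3.18, yet the list missed the threshold in camera (adjusted p = 0.057, and 0.71 with an estimated correlation). The camera adjusted p was 1.4e-69 without IGF1 replicate 1, whose levels of these genes enter the shared spread, and then 0.0018 with an estimated correlation. The list also passed without IGF1 replicate 2 or 3 (0.027 each), without a filter on low counts (0.0081) and with the replicate number as a block (0.048).

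**Figure D2:**
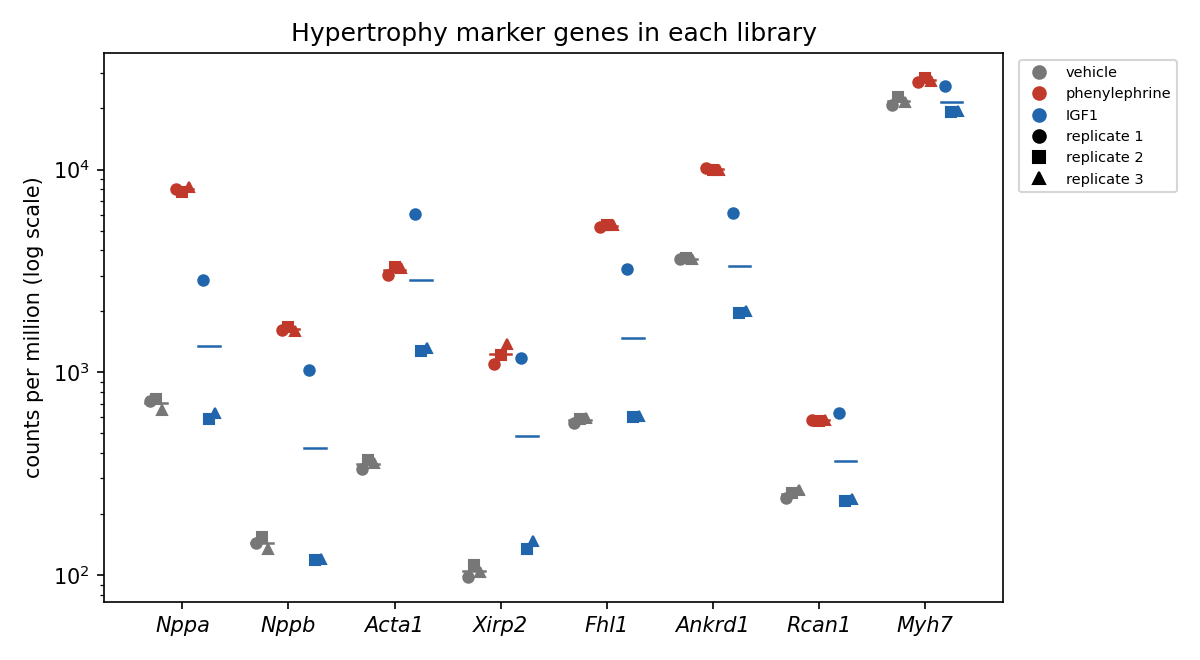
Levels of 8 hypertrophy markers in CPM on a log scale, with a point for each sample, shaped by replicate number, and a line at each group's mean. The phenylephrine samples lie at 7792 to 8246 CPM for Nppa, and IGF1 replicate 1 at 2848 CPM lies above IGF1 replicates 2 and 3 at 591 and 630 CPM.

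Among genes that met the naming rule, other large rises were those of Bdkrb2, a bradykinin receptor, from 1.83 ± 0.13 to 63.1 ± 3.35 CPM, Ptgis, the prostacyclin synthase, from 18.6 ± 2.57 to 221 ± 2.13 CPM, and Hsf2bp, Stmn4 and Syt12, which rose 15.6-fold, 12.2-fold and 10.5-fold. The largest falls under that rule were those of Asb14, Piwil2, Asb18, Slc25a34, Gnb3, Ptprr, Dhrs7c and Adhfe1, with log2 fold changes of -2.74 to -2.32. Asb14 fell from 30.3 ± 0.83 to 4.56 ± 0.66 CPM and the mitochondrial carrier Slc25a34 from 33.7 ± 0.87 to 5.99 ± 1.02 CPM.

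Of 21 cholesterol synthesis genes, 20 rose and none fell with phenylephrine (20 adjusted over the list alone; camera adjusted p = 8.6e-49), with Idi1 at 6.98-fold. With an estimated correlation the adjusted p was 0.0504, and 5.8e-04 with that and no IGF1 replicate 1. In fatty acid synthesis 11 of 13 genes rose and 2 fell (adjusted over the list alone, 11 and 2; adjusted p = 6.1e-11, and 0.030 with an estimated correlation), among them the desaturase Scd1 at 5.45-fold and the synthase Fasn at 2.75-fold, while Gpam and Acacb fell. Of 23 tested genes of fatty acid uptake and oxidation, 22 fell and none rose (22 adjusted over the list alone; adjusted p = 2.7e-13, and 0.088 with an estimated correlation). Hadh, an enzyme of beta-oxidation, was 2.65-fold lower and Pdk4, a kinase that inhibits pyruvate dehydrogenase, 2.40-fold lower.

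Glycolysis genes rose in 12 of 18 cases and fell in 3 (12 and 3 adjusted over the list alone), with the monocarboxylate carrier Slc16a3 at 2.98-fold, the phosphofructokinase Pfkp at 2.61-fold and the aldolase Aldoc 2.40-fold lower. That list missed the threshold (camera adjusted p = 0.23, and 0.75 with an estimated correlation). It passed without IGF1 replicate 1 (0.0090, but 0.40 with an estimated correlation) and without a filter on low counts (0.046). Pentose phosphate genes rose in 5 of 7 cases and fell in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.041, and 0.50 with an estimated correlation), and that call ended without IGF1 replicate 1 (0.19). Genes of oxidative phosphorylation and the TCA cycle rose in 9 of 31 cases and fell in 5 (9 and 5 adjusted over the list alone; adjusted p = 0.54), with Idh3a at 1.36-fold and Suclg1 1.31-fold lower, and without IGF1 replicate 1, 18 rose and 6 fell. Hexosamine pathway genes rose in 5 of 9 cases and fell in 2 (5 and 2 adjusted over the list alone; adjusted p = 0.31), with Gfpt2 at 1.66-fold and the O-GlcNAc transferase Ogt 1.30-fold lower.

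Of 22 immediate-early and ERK feedback genes, 17 rose and 1 fell (17 and 2 adjusted over the list alone; adjusted p = 1.7e-07, 0.34 with an estimated correlation, and 0.029 with that and no IGF1 replicate 1). The nuclear receptor Nr4a3 rose 7.22-fold and the stress factor Atf3 4.11-fold. The call of Atf3 ended when any 1 vehicle sample or phenylephrine replicate 1 or 2 was left out (log2 1.98 to 2.08, edgeR adjusted p = 0.0501 to 0.065). With IGF1 replicate 1 left out, its adjusted p was 2.1e-26 at log2 2.04. Targets of ATF4, a regulator of amino acid supply, rose in 12 of 17 cases and fell in 2 (12 and 2 adjusted over the list alone; adjusted p = 6.7e-05, and 0.40 with an estimated correlation), with Mthfd2 at 4.41-fold and Asns at 3.42-fold, and Atf4 itself rose 1.71-fold. Ribosome biogenesis genes rose in 18 of 23 cases and fell in 2 (18 and 2 adjusted over the list alone; adjusted p = 2.1e-04, and 0.69 with an estimated correlation), including Myc at 2.08-fold. FoxO targets and atrophy genes fell in 15 of 20 cases and rose in 2 (15 and 2 adjusted over the list alone; adjusted p = 6.2e-09, 0.065 with an estimated correlation, and 0.049 with that and no IGF1 replicate 1). Pik3ip1 was 3.44-fold and the ubiquitin ligase Fbxo32 2.42-fold lower, whereas Irs2 and Cited2 rose.

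Cell cycle genes fell in 18 of 26 cases and rose in 2 (19 and 2 adjusted over the list alone; adjusted p = 0.0050, and 0.71 with an estimated correlation), with Cenpf 1.81-fold lower and the cyclin D1 gene Ccnd1 1.23-fold higher. The call of Ccnd1 ended without vehicle replicate 3 (log2 0.26, edgeR adjusted p = 0.052) and with scaling by library size only (0.15). Its adjusted p was 9.4e-10 without IGF1 replicate 1. Adult ion handling genes fell in 11 of 16 cases and rose in 4 (11 and 4 adjusted over the list alone; adjusted p = 0.0050, and 0.31 with an estimated correlation), with the potassium channel Kcnj2 2.36-fold lower and the exchanger Slc8a1 1.57-fold higher. Members of that list ran from log2 -4.27 to 0.88. Sarcomere genes rose in 11 of 18 cases and fell in 3 (11 and 3 adjusted over the list alone; adjusted p = 0.041, and 0.71 with an estimated correlation), with Csrp3 at 4.38-fold and Myom2 1.46-fold lower. Without vehicle replicate 1, the adjusted p was 0.061 for the sarcomere list and 0.053 for Csrp3 (log2 2.08). With IGF1 replicate 1 left out, it was 5.4e-11 for the list (0.17 with an estimated correlation) and 1.9e-34 for Csrp3 (log2 2.13). Csrp3 lay at 1404 CPM in IGF1 replicate 1, against 382 and 398 CPM in IGF1 replicates 2 and 3.

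Genes of adrenergic and Gq signalling rose in 5 of 22 cases and fell in 9 (5 and 9 adjusted over the list alone; camera adjusted p = 0.60). The receptor gene Adra1a was 1.57-fold higher, and Adra1b and Adra1d were 1.94-fold and 3.73-fold lower. IGF and insulin signalling genes rose in 4 of 16 cases and fell in 8 (4 and 8 adjusted over the list alone; adjusted p = 0.55), with the receptor Igf1r 1.44-fold higher and the binding protein Igfbp3 2.19-fold lower. Endoplasmic reticulum chaperone genes rose in 9 of 20 cases and fell in 3 (9 and 3 adjusted over the list alone; adjusted p = 0.23), with Dnajb11 at 1.55-fold. Extracellular matrix genes rose in 8 of 22 cases and fell in 8 (8 and 9 adjusted over the list alone), with the growth factor Tgfb2 at 3.46-fold, Timp1 at 2.78-fold and the collagen Col3a1 1.35-fold lower. The matrix list had a median of -0.069, a mean of 0.30 and an upward test (adjusted p = 0.17), and passed without IGF1 replicate 1 (7.7e-05, but 0.40 with an estimated correlation). Inflammatory genes rose in 5 of 13 cases and fell in 2 (5 and 2 adjusted over the list alone; adjusted p = 0.89), with the cytokine receptor Tnfrsf12a at 7.30-fold and the chemokine Cxcl10 2.72-fold lower. Interferon response genes fell in 3 of 20 cases and none rose (1 adjusted over the list alone; adjusted p = 0.31). Their mean was -0.81, and -0.19 without vehicle replicate 3 (adjusted p = 0.53), in which they stood apart by a median log2 of 0.67.

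No list of markers of other cell types passed the threshold with phenylephrine. Smooth muscle and pericyte markers rose in 5 of 10 cases and fell in 3 (5 and 4 adjusted over the list alone; camera adjusted p = 0.47), with Cnn1 at 5.64-fold, and that list passed without IGF1 replicate 1 (2.9e-05, but 0.17 with an estimated correlation). Fibroblast markers rose in 1 of 11 cases and fell in 2, and endothelial markers in 1 and 1 of 10 (adjusted p = 0.78 and 0.90), with 3 endothelial falls without IGF1 replicate 1. Macrophage and leukocyte markers fell in 3 of 10 cases (median 0.010, mean -0.084, downward test, adjusted p = 0.78). Epicardial markers rose in 2 of 7 cases and fell in 3, Schwann cell markers fell in 1 of 4, and the 1 erythroid gene passed in neither direction (adjusted p = 0.89, 0.55 and 0.89). Adjusted over the list alone, the counts of these 6 lists were the same.

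The split of calls depended on scaling. With scaling by library size only, 1751 genes were higher and 5696 lower, so that 23.5% of calls were higher in place of 49.1%, and the median over all genes moved from -0.03 to -0.22 (log2). The small rises of the pentose phosphate enzyme Taldo1 and the hexosamine pathway enzyme Gfpt1 (log2 0.17 and 0.18) became -0.022 and -0.016 under that scaling. The log2 fold changes of Myh6, Idh3a, Cited2 and Igf1r (0.30, 0.45, 0.53 and 0.52) became 0.11, 0.25, 0.34 and 0.33, and those of Suclg1 and Ogt (-0.39 and -0.38) both became -0.58. The call of Gfpt1 also ended without vehicle replicate 2 or 3 or phenylephrine replicate 3 (edgeR adjusted p = 0.057, 0.081 and 0.081). Its adjusted p was 0.0010 without IGF1 replicate 1.

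IGF1 against vehicle addressed the response to the growth factor. Among genes that met the naming rule, large rises were those of Myo16 (8.99-fold), Acta1 (8.13-fold), the mitochondrial creatine kinase Ckmt2 (7.77-fold), Sypl2 (7.15-fold), the calcium store protein Casq1 (6.43-fold), Slc17a7 (5.67-fold) and Crhr2 (4.04-fold). Ckmt2 rose from 5.99 ± 0.36 to 46.6 ± 1.06 CPM (SD, n = 3; log2 2.96, SE 0.08, edgeR adjusted p = 2.2e-12). The largest falls under that rule were those of the sarcomere gene Myom2, Hamp, Lrtm2, Gnb3, Pbld1, Pla2g7, Dpysl5 and Maff, which were 4.14-fold to 5.72-fold lower. Myom2 fell from 2688 ± 80.8 to 470 ± 30.1 CPM. The rises of Acta1, Sypl2 and Casq1 (log2 3.02, 2.84 and 2.68) were 1.87, 1.42 and 1.28 without IGF1 replicate 1 (adjusted p = 4.6e-23, 1.8e-12 and 5.3e-05). The calls of Sypl2 and Casq1 ended when any 1 vehicle or phenylephrine sample was left out (log2 2.64 to 2.87, adjusted p = 0.053 to 0.10), when only these 2 groups were fitted (0.089 for each) and with the replicate number as a block (0.085 and 0.080).

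In all, 2935 genes were higher and 2781 lower with IGF1, of which 272 and 253 changed at least 2-fold. Scaling by library size only gave 2031 higher and 3614 lower, so that 36.0% of calls were higher in place of 51.3%. Leaving out IGF1 replicate 1 gave 3292 and 3194. Of the 5716 calls, 5445 were also called in the same direction without it, 271 were lost and 1018 were gained.

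Cell cycle genes rose in 24 of 26 cases and none fell (24 adjusted over the list alone; camera adjusted p = 1.3e-30, and 0.080 with an estimated correlation). The cyclin gene Ccnb1 rose 3.82-fold and Ccnb2 3.46-fold, the latter from 19.4 ± 1.31 to 67.0 ± 5.57 CPM. Of 31 genes of oxidative phosphorylation and the TCA cycle, 30 rose and none fell (30 adjusted over the list alone; adjusted p = 2.0e-08, and 0.84 with an estimated correlation), with Ndufs1 at 1.64-fold and citrate synthase Cs at 1.51-fold. Glycolysis genes rose in 13 of 18 cases and fell in 1 (15 and 1 adjusted over the list alone; adjusted p = 8.0e-06, and 0.35 with an estimated correlation), with Slc16a3 at 2.52-fold and Ldha at 1.74-fold. Genes of fatty acid uptake and oxidation rose in 10 of 23 cases and fell in 6 (10 and 6 adjusted over the list alone), with Acsl1 at 1.63-fold and Pdk4 2.35-fold lower, and the list had a median of 0.08, a mean of -0.0099 and a downward test (adjusted p = 0.86). Hexosamine pathway genes rose in 1 of 9 cases and fell in 3 (0 and 3 adjusted over the list alone; adjusted p = 0.84), and pentose phosphate genes rose in 2 of 7 and fell in 1 (2 and 1 adjusted over the list alone; adjusted p = 0.84), with Rpe at 1.40-fold.

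Cholesterol synthesis genes rose in 19 of 21 cases and none fell (19 adjusted over the list alone; adjusted p = 1.3e-17, 0.22 with an estimated correlation, and 0.0023 with that and no IGF1 replicate 1). Fatty acid synthesis genes rose in 11 of 13 cases and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 6.8e-13, and 0.018 with an estimated correlation), with Scd2 at 3.64-fold. FoxO targets and atrophy genes fell in 19 of 20 cases and rose in 1 (19 and 1 adjusted over the list alone; adjusted p = 1.1e-14, and 0.022 with an estimated correlation). The thioredoxin inhibitor Txnip was 2.69-fold lower and the insulin receptor substrate Irs2 2.14-fold lower, while Sesn3 was 1.94-fold higher. IGF and insulin signalling genes rose in 7 of 16 cases and fell in 6 (7 and 7 adjusted over the list alone), with Pik3r3 at 2.36-fold, the receptor Igf1r 1.52-fold lower and the binding protein Igfbp2 2.23-fold lower. That list had a median of -0.11, a mean of 0.015 and an upward test (adjusted p = 0.86).

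Of 22 immediate-early and ERK feedback genes, 15 fell and none rose (15 adjusted over the list alone; camera adjusted p = 4.0e-05, and 0.58 with an estimated correlation), with Fosl2 1.78-fold lower. Leaving out IGF1 replicate 1, 20 fell, and the adjusted p with an estimated correlation was 0.012. Ribosome biogenesis genes rose in 7 of 23 cases and fell in 8 (8 and 8 adjusted over the list alone), with Myc 2.20-fold lower, and the list had a median of 0.051, a mean of -0.045 and a downward test (adjusted p = 0.84). ATF4 targets rose in 7 of 17 cases and fell in 3 (7 and 3 adjusted over the list alone; adjusted p = 0.15, and 0.95 with an estimated correlation), with Psat1 at 1.87-fold and Trib3 1.55-fold lower, and that list passed without vehicle replicate 1 (0.047). Leaving out IGF1 replicate 1, 9 rose and 5 fell. Mthfd2 of that list lay at 157, 71.9 and 69.2 CPM in IGF1 replicates 1, 2 and 3, and its log2 fold change of 1.26 was 0.77 without replicate 1 (edgeR adjusted p = 1.6e-19). The call of Mthfd2 ended when any 1 vehicle sample was left out (edgeR adjusted p = 0.061 to 0.065) and when only these 2 groups were fitted (0.064). Endoplasmic reticulum chaperone genes rose in 2 of 20 cases and fell in 9 (2 and 9 adjusted over the list alone; adjusted p = 0.22), with Herpud1 1.53-fold lower. Extracellular matrix genes rose in 4 of 22 cases and fell in 10 (5 and 10 adjusted over the list alone; adjusted p = 0.23, and without IGF1 replicate 1 5.8e-07, but 0.38 with an estimated correlation), with Postn at 1.66-fold and the crosslinking enzyme Lox 1.82-fold lower. These counts were 6 and 13 without that sample.

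Adrenergic and Gq signalling genes rose in 4 of 22 cases and fell in 3 (4 and 3 adjusted over the list alone; camera adjusted p = 0.92). Adra1a and Adra1b stood at log2 0.08 and -0.063 (edgeR adjusted p = 0.60 and 0.56), and Adra1a at 0.21 without IGF1 replicate 1 (0.028) and -0.040 without replicate 3 (0.81). Gfpt1 stood at 0.068 (adjusted p = 0.35), at 0.12 without IGF1 replicate 1 (0.044) and at -0.013 with scaling by library size only. Inflammatory genes rose in 3 of 13 cases and fell in 3 (3 and 3 adjusted over the list alone; camera adjusted p = 0.72), with Cxcl10 3.66-fold lower. Of 20 interferon response genes, Mx1 rose and none fell (0 adjusted over the list alone; camera adjusted p = 0.84). The mean of that list was 0.40, and -0.26 without IGF1 replicate 2 and 1.03 without vehicle replicate 3 (adjusted p = 0.80 and 0.31). The call of Mx1 (log2 1.76) ended without IGF1 replicate 2 (edgeR adjusted p = 0.14) and without vehicle replicate 1 or 2 (0.083 and 0.072).

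Endothelial markers fell in 5 of 10 cases and none rose with IGF1 (5 adjusted over the list alone; camera adjusted p = 0.031, and 0.24 with an estimated correlation), with the receptor Kdr 3.40-fold lower, from 44.7 ± 4.32 to 13.1 ± 1.67 CPM. The adjusted p of that list was 0.16 without IGF1 replicate 1. Fibroblast markers rose in 3 of 11 cases and fell in 2 (median -0.039, mean 0.08, upward test, adjusted p = 0.84), with Lum at 1.81-fold and Pdgfra 1.31-fold lower. Smooth muscle and pericyte markers rose in 1 of 10 cases and fell in 2, and macrophage and leukocyte markers fell in 1 of 10 (adjusted p = 0.86 and 0.80). The former rose in 4 cases and fell in 3 without IGF1 replicate 1. Epicardial markers fell in 3 of 7 cases (median 0.12, mean -0.17, downward test, adjusted p = 0.80) and Schwann cell markers in 1 of 4 (median 0.11, mean 0.051, downward test, adjusted p = 0.84), and the 1 erythroid gene passed in neither direction (0.84). Adjusted over the list alone, the counts of these 6 lists were the same.

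The hypertrophy markers differed between the IGF1 samples. Nppa lay at 2848, 591 and 630 CPM in IGF1 replicates 1, 2 and 3, Nppb at 1031, 119 and 121 CPM, and Acta1 at 6019, 1268 and 1317 CPM, against 705 ± 46.3, 145 ± 9.42 and 353 ± 17.2 CPM (SD, n = 3) with vehicle. Over all 3 IGF1 samples Nppa and Nppb did not pass the threshold (log2 0.94 and 1.55, edgeR adjusted p = 0.27 and 0.20). Without replicate 1 they were lower than with vehicle (log2 -0.21 and -0.27, adjusted p = 4.1e-04 and 4.6e-07). Rcan1, Atf4 and Myh7 stood at 0.53, 0.08 and -0.011 over all samples (adjusted p = 0.32, 0.67 and 0.94) and at -0.10, -0.12 and -0.17 without it (0.0099, 0.0015 and 1.4e-04). Myh7 stood at 0.018 without vehicle replicate 2 and at 0.057 and 0.049 without IGF1 replicate 2 or 3, and Atf4 at -0.016 with scaling by library size only. Of the 8 markers, Acta1 alone passed the threshold over all samples (1 adjusted over the list alone), whereas without replicate 1, 2 were higher and 5 lower. The list passed neither with replicate 1 (camera adjusted p = 0.80) nor without it (0.93).

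Sarcomere genes rose with IGF1 in 13 of 18 cases and fell in 1, Myom2 (13 and 1 adjusted over the list alone; camera adjusted p = 0.23, and 0.95 with an estimated correlation). That list passed without IGF1 replicate 1 (0.027, but 0.94 with an estimated correlation) or 2 (0.048) and without a filter on low counts (0.0064). Adult ion handling genes rose in 5 of 16 cases and fell in 4 (5 and 4 adjusted over the list alone), with Myh6 at 1.57-fold and the potassium channel Kcnd3 1.78-fold lower, and the list had a median of 0.07, a mean of -0.17 and an upward test (adjusted p = 0.86). Its members ran from log2 -3.99 to 0.65. Atp2a2 was 1.09-fold lower (edgeR adjusted p = 0.022), a call that ended without vehicle replicate 2 (0.084) and when only these 2 groups were fitted (0.051), and its log2 fold change of -0.13 was -0.21 with scaling by library size only.

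**Figure D3:**
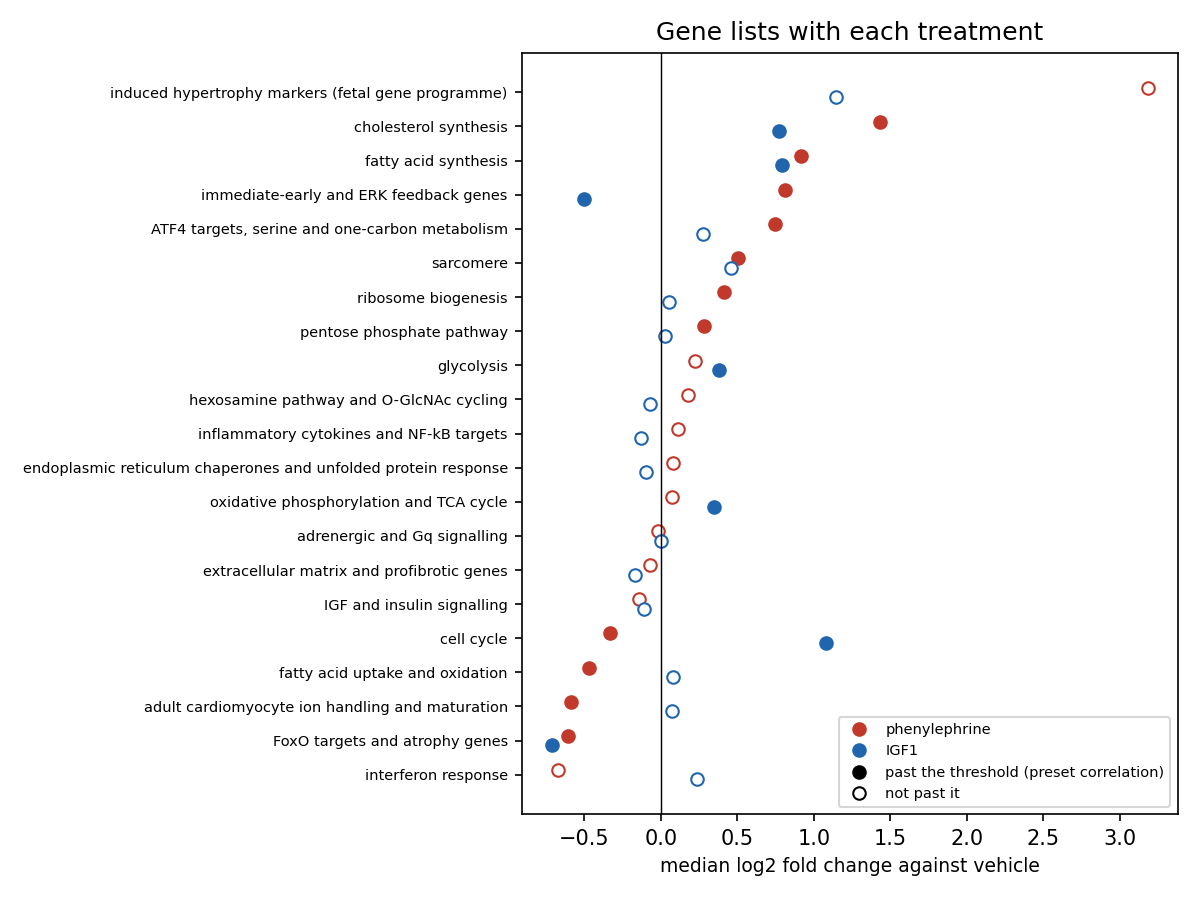
Median log2 fold change against vehicle over the tested members of each of the 21 gene lists, for phenylephrine and IGF1, filled where camera with the preset correlation passed the threshold. Cell cycle genes lie at 1.08 with IGF1 and -0.33 with phenylephrine, and immediate-early genes at -0.51 and 0.81.

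Phenylephrine against IGF1 tested the difference between the stimuli. Ptgis was 15.2-fold, Bdkrb2 13.0-fold, Syt12 11.4-fold, Lypd1 9.92-fold, the growth factor gene Areg 9.87-fold and Rnf39 8.34-fold higher with phenylephrine. Myo16 was 25.7-fold, Ky 24.2-fold, the developmental myosin Myh8 11.4-fold, Ckmt2 10.4-fold and Piwil2 9.95-fold lower. Bdkrb2 lay at 14.7, 0.63 and 1.11 CPM in IGF1 replicates 1, 2 and 3, and its log2 difference of 3.70 (edgeR adjusted p = 0.014) was 6.16 without replicate 1, while its call ended when only these 2 groups were fitted (0.054). Of the genes tested, 3215 were higher and 3222 lower with phenylephrine than with IGF1, of which 399 and 633 differed at least 2-fold. Scaling by library size only gave 2132 higher and 4366 lower, so that 32.8% of calls were higher in place of 49.9%.

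Of 8 hypertrophy markers, 3 were higher with phenylephrine than with IGF1 and none lower (3 adjusted over the list alone), with a median of 1.46 and a camera adjusted p of 0.20. Nppa was 5.91-fold higher (log2 2.56, edgeR adjusted p = 0.017, and 0.058 when only these 2 groups were fitted) and Myh7 1.28-fold higher. Nppb, Rcan1 and Acta1 stood at 1.95, 0.67 and 0.16 and did not pass (adjusted p = 0.11, 0.21 and 0.85). Leaving out IGF1 replicate 1 left all 8 higher, with a median of 2.73 (camera adjusted p = 1.7e-57, and 0.0017 with an estimated correlation), and Nppa, Nppb, Rcan1 and Acta1 stood at 3.72, 3.77, 1.30 and 1.31. Acta1 stood at -0.20 and -0.19 without IGF1 replicate 2 or 3. Sarcomere genes were higher in 6 of 18 cases and lower in 5 (6 and 5 adjusted over the list alone; adjusted p = 0.50, and without IGF1 replicate 1 6.4e-06, but 0.36 with an estimated correlation), with Myom2 3.92-fold higher and the troponin Tnni3 1.53-fold lower. These counts were 10 and 6 without that sample. Adult ion handling genes were lower in 9 of 16 cases and higher in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.0056, and 0.38 with an estimated correlation), with Kcnj2 2.11-fold, Atp2a2 1.40-fold and Myh6 1.28-fold lower.

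All 22 immediate-early and ERK feedback genes were higher with phenylephrine (22 adjusted over the list alone; camera adjusted p = 5.5e-17, 0.15 with an estimated correlation, and 0.0017 with that and no IGF1 replicate 1), with Nr4a3 at 7.78-fold and Fos at 3.96-fold. The call of Fosl2 (log2 0.35, edgeR adjusted p = 0.039) ended without vehicle replicate 1, phenylephrine replicate 1 or 2, or IGF1 replicate 1 or 3 (0.056, 0.10, 0.12, 0.090 and 0.075), when only these 2 groups were fitted (0.064) and with scaling by library size only (0.19). Of 26 cell cycle genes, 25 were lower and 1 higher (25 and 1 adjusted over the list alone; adjusted p = 8.7e-33, and 0.15 with an estimated correlation), with Ccnb2 5.97-fold lower. Ribosome biogenesis genes were higher in 19 of 23 cases and none lower (20 adjusted over the list alone; adjusted p = 1.7e-04, and 0.64 with an estimated correlation), with Myc at 4.58-fold. ATF4 targets were higher in 10 of 17 cases and lower in 4 (11 and 4 adjusted over the list alone; adjusted p = 0.033, and 0.67 with an estimated correlation), with Slc3a2 at 2.63-fold and Psat1 1.47-fold lower, and Atf4 itself was 1.62-fold higher. Endoplasmic reticulum chaperone genes were higher in 13 of 20 cases and none lower (13 adjusted over the list alone; adjusted p = 0.011, and 0.64 with an estimated correlation), with Sdf2l1 at 1.45-fold, and without IGF1 replicate 1, 14 were higher and 2 lower. Extracellular matrix genes were higher in 13 of 22 cases and lower in 6 (13 and 7 adjusted over the list alone; adjusted p = 0.011, and 0.64 with an estimated correlation), with Postn 2.00-fold lower. Tgfb2 of that list was higher by 1.73 (log2), and by 2.44 without IGF1 replicate 1, but its call ended when only these 2 groups were fitted (0.059).

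Of 21 cholesterol synthesis genes, 19 were higher with phenylephrine than with IGF1 and none lower (19 adjusted over the list alone; camera adjusted p = 4.0e-12, 0.38 with an estimated correlation, and 0.0017 with that and no IGF1 replicate 1), with Fdps at 3.17-fold. Genes of fatty acid uptake and oxidation were lower in 21 of 23 cases and none higher (21 adjusted over the list alone; adjusted p = 1.2e-11, and 0.15 with an estimated correlation), with Hadh 2.94-fold lower. Those of oxidative phosphorylation and the TCA cycle were lower in 27 of 31 cases and none higher (27 adjusted over the list alone; adjusted p = 2.9e-04, and 0.72 with an estimated correlation). Glycolysis genes were lower in 9 of 18 cases and higher in 3 (9 and 3 adjusted over the list alone; adjusted p = 0.037, and 0.67 with an estimated correlation), with Aldoc 3.08-fold lower. The glycolysis call ended without IGF1 replicate 1 (0.087, with 8 lower and 5 higher) and without phenylephrine replicate 2 (0.053). Fatty acid synthesis genes were higher in 6 of 13 cases and lower in 5 (6 and 5 adjusted over the list alone; adjusted p = 0.70), hexosamine pathway genes higher in 4 of 9 and lower in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.18), and pentose phosphate genes higher in 4 of 7 and lower in 2 (4 and 2 adjusted over the list alone; adjusted p = 0.13).

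FoxO targets and atrophy genes were higher in 6 of 20 cases and lower in 8 (6 and 11 adjusted over the list alone), with Irs2 3.42-fold higher and Sesn3 2.04-fold lower, and the list had a median of -0.18, a mean of 0.029 and an upward test (camera adjusted p = 0.63). Without IGF1 replicate 1, 7 were higher and 12 lower. IGF and insulin signalling genes were higher in 5 of 16 cases and lower in 8 (5 and 8 adjusted over the list alone; adjusted p = 0.50), with Igf1r 2.19-fold higher and Igfbp3 3.49-fold lower. Adrenergic and Gq signalling genes were higher in 7 of 22 cases and lower in 7 (7 and 7 adjusted over the list alone), with Adra1a 1.49-fold higher and Adra1d 5.50-fold lower, and the list had a median of 0.017, a mean of -0.13 and a downward test (adjusted p = 0.58). Inflammatory genes were higher in 4 of 13 cases and lower in 2 (4 and 2 adjusted over the list alone; adjusted p = 0.50, and without IGF1 replicate 1 0.021, but 0.17 with an estimated correlation), with the cyclooxygenase Ptgs2 2.06-fold higher. Interferon response genes were lower in 6 of 20 cases and none higher (4 adjusted over the list alone; adjusted p = 0.18, and 0.79 with an estimated correlation), and that list passed without a filter on low counts (0.049). These genes stood apart in IGF1 replicate 2, by a median log2 of 1.12 from the other IGF1 samples, and the mean of the list was -1.21 over all samples and -0.56 without it (adjusted p = 0.28).

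Markers of other cell types passed as a list in no case between the treatments. Endothelial markers were higher with phenylephrine in 4 of 10 cases and none lower (4 adjusted over the list alone; camera adjusted p = 0.10), with Egfl7 2.99-fold and Kdr 2.17-fold higher. Smooth muscle and pericyte markers were higher in 6 of 10 cases and lower in 3 (6 and 3 adjusted over the list alone; adjusted p = 0.58, and without IGF1 replicate 1 1.8e-04, but 0.22 with an estimated correlation), with Cnn1 4.11-fold higher. Fibroblast markers were higher in 1 of 11 cases and lower in 3 (1 and 3 adjusted over the list alone; median 0.0099, mean -0.16, downward test, adjusted p = 0.56), and 5 were lower without IGF1 replicate 1. Macrophage and leukocyte markers were higher in 2 of 10 cases and lower in 1 (1 and 1 adjusted over the list alone; adjusted p = 0.84), and epicardial markers higher in 1 of 7 and lower in 1 (1 and 1 adjusted over the list alone; adjusted p = 0.70). None of 4 Schwann cell markers and 1 erythroid gene passed (0 and 1 adjusted over the list alone; adjusted p = 0.70 for each).

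Across the 11873 genes, which are not independent replicates, the fold changes of the treatments against the shared vehicle samples had a Pearson r of 0.329. Unchanged groups simulated against shared controls gave a mean r of 0.464. Those groups held no true change, so their r came from the shared controls alone and does not show how much of 0.329 did. By itself r therefore does not separate a shared effect from shared controls. The covariance was 0.0963 against 0.0114 in the simulations, a difference of 0.0850. Both treatments raised 1466 genes (818 if the calls were independent) and lowered 1482 (803 if independent). A further 377 genes were higher with phenylephrine and lower with IGF1 (775 if independent), and 579 the reverse (848 if independent). These numbers for independent calls take no account of the shared vehicle samples. Separate vehicle samples for each treatment, 1 for the one and 2 for the other, were tried after seeing the data, on log2 CPM differences. Over the 6 ways r was 0.230 to 0.304 and the covariance 0.0658 to 0.0827. The same measure with all vehicle samples shared gave 0.325 and 0.0862. Thus r stayed positive where the treatments shared no vehicle sample. Without IGF1 replicate 1, r was 0.209 and the covariance 0.0637. The genes higher with phenylephrine and lower with IGF1 were then 743 (995 if independent) and the reverse 807 (1060 if independent), and 67.8% of the genes that passed in both comparisons moved the same way, against 75.5% with all samples.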

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

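The tests of explanations in this part were chosen after the result was seen, except the counts over other splits of the samples. A difference between the treatments, tested directly, singled out 2 gene lists that the treatments moved in opposite directions. The median log2 difference, phenylephrine minus IGF1, was 1.36 for the immediate-early and ERK feedback genes and -1.49 for the cell cycle genes. Neither difference passed the threshold with an estimated correlation (adjusted p = 0.15 for each). Without IGF1 replicate 1 and with an estimated correlation, the adjusted p was 0.0017 for the immediate-early genes and 0.13 for the cell cycle genes.

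The cell cycle genes, higher with IGF1 and lower with phenylephrine, were weighed further. A higher share of fibroblasts with IGF1 would raise fibroblast markers by about as much as the cell cycle list, whose median was 1.08. The fibroblast median was -0.039 with an SD of 0.40 over members. Of 11 fibroblast markers, 3 rose and 2 fell, with log2 fold changes from -0.39 to 0.86. The most abundant of them, Col14a1, lay at 302 ± 35.2 CPM with IGF1 against 380 ± 17.4 CPM with vehicle (SD, n = 3). No fibroblast marker reached the cell cycle median, which argues against a higher share of fibroblasts as the whole cause. IGF1 replicate 1 alone is argued against as well, since the median without it was 1.13. Which cells of the culture carried the cell cycle transcripts was not measured, so a change in myocytes and a change in dividing cells of another type both stay open, next to an effect of the treatments.

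The 10 splits of 6 samples into 3 and 3 are too few for a share under 0.05. The real split was 1 of 10 to reach its count in each comparison. It changed 6739 genes for phenylephrine against vehicle, 5716 for IGF1 against vehicle and 6437 for phenylephrine against IGF1, and the highest other split changed 0 genes in each (edgeR). At an unadjusted p under 0.05 the other splits gave up to 164, 533 and 743 genes, against 7270, 6458 and 7003 for the real ones. Every other split mixes samples of both groups, so the difference between the groups enters its spread. Low counts in the other splits follow from that design, and no conclusion is drawn from them.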

How the results depend on the processing

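The estimated correlation combined with leaving out IGF1 replicate 1, and separate vehicle samples for each treatment (mean r 0.268), were chosen after seeing the data. Over 5395 alternative values of named genes, 5125 kept direction and side of the threshold, 246 were no longer past it, 9 were newly past it and 15 reversed. Over 1176 alternative values of gene lists the numbers were 1087, 52, 21 and 16. In 9 of the 15 and all 16 of the reversals neither value passed the threshold. These totals do not cover every alternative. Named genes were not tried under limma-voom, upper-quartile factors, the stricter filter or other thresholds. Lists were not tried under any of these, nor under DESeq2, scaling by library size only or a fit of the 2 groups compared alone. For the alternatives below the cause was not tested, unless given. With scaling by library size only, 1751 genes were higher and 5696 lower for phenylephrine against vehicle and 2132 higher for phenylephrine against IGF1, and that scaling moved the median of all genes. Reversed log2 fold changes under it were -0.022 for Taldo1 and -0.016 for Gfpt1 (phenylephrine against vehicle), -0.013 for Gfpt1 and -0.016 for Atf4 (IGF1 against vehicle), and -0.0030 for Gfpt1 (phenylephrine against IGF1). Requiring a 2-fold change left 361 higher and 492 lower, 272 and 253, and 399 and 633, since most changes were smaller. With an estimated correlation, 1, 2 and 0 lists passed in place of 11, 8 and 11, and with that and no IGF1 replicate 1, 5, 4 and 3. In the latter, the mean of fatty acid oxidation genes (IGF1 against vehicle) was 0.023, and for phenylephrine against IGF1 that of macrophage markers was -0.077 and of epicardial markers -0.039, all reversed. Without a filter on low counts, the fatty acid oxidation list with IGF1 (mean -0.0058) reversed in test direction.

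Leaving out 1 sample at a time, r of the fold changes ranged from 0.209, without IGF1 replicate 1, to 0.386. For IGF1 against vehicle, log2 fold changes ranged from -0.21 to 1.29 for Nppa, -0.27 to 1.98 for Nppb, -0.10 to 0.77 for Rcan1, -0.12 to 0.16 for Atf4, -0.17 to 0.057 for Myh7 and -0.040 to 0.21 for Adra1a. The lowest of each but Adra1a came without IGF1 replicate 1. Acta1, phenylephrine against IGF1, ranged from -0.20 to 1.31. List means that reversed in test direction, none past the threshold, ranged with IGF1 from -0.0033 to 0.047 for adrenergic signalling, -0.023 to 0.047 for fatty acid oxidation and -0.26 to 1.03 for the interferon response. With phenylephrine against vehicle they ranged from -0.20 to -0.046 for endothelial and -0.096 to 0.33 for macrophage markers, and against IGF1 from -0.084 to 0.12 for macrophage and -0.039 to 0.14 for epicardial markers.

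With the replicate number as a block, 3253 genes were higher and 3395 lower with phenylephrine, 2871 and 2723 with IGF1, and 3167 and 3145 between them. Under it the calls of Rcan1 with phenylephrine and of Sypl2 and Casq1 with IGF1 ended (edgeR adjusted p = 0.066, 0.085 and 0.080), among others, and the hypertrophy list with phenylephrine passed (0.048). Same-numbered samples had correlations of deviations from -0.085 to 0.021, and 1 of 9 samples correlated best with its own number, so the numbers were not taken to pair samples. Depth and number of samples were not varied. With few genes changed, the smallest simulated changes were recovered for 41.7% of genes for phenylephrine against vehicle. That simulation gave 172 calls and the data 6739, so the share need not hold for the data. A level of 1 CPM rested on 29.1 to 51.6 reads.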

Other observations

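The tests in this part were chosen after the results were seen, and so were the genes of its first paragraph. Myoglobin Mb rose with IGF1 (log2 1.16, edgeR adjusted p = 4.6e-10) and fell with phenylephrine (-1.39, adjusted p = 5.7e-11), as did the carbonic anhydrase Car3 (1.53 and -1.03). The muscle enolase Eno3 rose with both (1.93 and 1.10). Phenylephrine minus IGF1, the direct differences were -2.55 for Mb, -2.56 for Car3 and -0.83 for Eno3 (adjusted p = 1.9e-13, 1.2e-08 and 3.3e-09). The pacemaker channel gene Hcn4 rose with IGF1 (1.21, adjusted p = 4.4e-09) and stood at 0.06 with phenylephrine (adjusted p = 0.50), and the direct difference was -1.15 (adjusted p = 4.4e-09). Of 11 antioxidant and glutathione genes, none rose and 8 fell with IGF1, with Gstp1 at -1.36 and Hmox1 at -0.79, and 5 rose and 3 fell with phenylephrine, with Srxn1 at 0.86 and Gstt2 at -0.78.

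IGF1 replicate 1 stood apart from the mean of IGF1 replicates 2 and 3, from which 55 of 9280 genes at 5 CPM or more differed over 2-fold, 53 of them higher and all 55 towards the phenylephrine level, though Mx2, 1 of these, lay between replicates 2 and 3 (12.0 against 60.5 and 5.36 CPM). RNA of the phenylephrine cultures in this library would need about the same percent for each gene. But the interquartile range of the needed percent was 40.0 points wide over the 50 of these genes with phenylephrine over 2-fold from replicates 2 and 3. Of the 55 genes, 13 lay above all 3 phenylephrine libraries. The 7 genes high only with phenylephrine, chosen without regard to replicate 1, needed a median of 56.2%. They ran from 4.10% for Ptgis, 11.9-fold higher with phenylephrine than with vehicle, to 115%, and Nppb needed 60.3%. A higher share of cardiomyocytes would raise cardiomyocyte genes alike. The median log2 difference was 0.39 over the sarcomere genes, -0.036 over the adult cardiomyocyte genes and 0.12 (SD 0.47) over both, and -0.24 over the fibroblast markers. The median was 1.49 for the genes higher in this library, which is large because they were chosen as over 2-fold apart. The values argue against a higher share as the cause of these over 2-fold differences, but a small rise in share stays open. Cells of another preparation, with another mix of male and female pups, stay open, since the Y-linked Ddx3y, at 32 reads, was at 0.416 of its level in replicates 2 and 3, but this is a single gene that can share reads with Ddx3x, the phenylephrine libraries lay at 1.93 to 2.09 CPM (by total counts) against 2.56 to 2.94 with vehicle, and the spread between preparations is unknown. A difference in the culture or its stimulation stays open too and was not tested, as the labels give this sample no difference from its group.

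Interferon-induced genes differed between samples of 1 group, with a median log2 difference from the other samples of the group of 1.12 in IGF1 replicate 2 and 0.67 in vehicle replicate 3, and Mx2 lay at 60.5 CPM in the former. Of the 28 genes over 1.5-fold apart between IGF1 replicates 2 and 3, 10 were in the interferon list. More macrophages or leukocytes carrying these transcripts would raise their own markers about as much. The markers' median difference in IGF1 replicate 2 and vehicle replicate 3 was 0.13 (SD 0.21), against a mean of 0.90 for the interferon genes. The abundant Lyz2 lay at 40.0 CPM in vehicle replicate 3 beside 39.2 and 34.7 CPM in replicates 1 and 2. In IGF1 replicate 2 it lay at 29.2 CPM beside 30.1 and 26.3 CPM in replicates 1 and 3. These values argue against more such cells as carriers of the transcripts, while an effect of such cells on others was not tested. Counting error is argued against for the 5 interferon genes at a mean of 20 CPM or more. All 5 were higher in IGF1 replicate 2 than in replicate 3 past a Bonferroni-adjusted exact binomial test. Interferon genes at lower levels, Mx2 among them, and vehicle replicate 3 were not covered by it. This pair differed by more than sampling noise over all genes too (chi-square per degree of freedom 4.50), so such a result is not particular to interferon genes. What the samples met in culture stays open and was not tested.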
